A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

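Expression was measured on 14 Affymetrix YG_S98 arrays of total RNA from budding yeast grown to mid-log phase in complete synthetic medium, per the labels' protocols. There were 4 arrays each of H3del and H3WT and 3 arrays each of H4del and H4WT. The deposited values are signal intensity on a linear scale, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. The 2% trimmed mean of each array lay between 1500.83 and 1501.18, a spread of 0.0232%, so the arrays were taken as already scaled and were not rescaled. Of 9335 probe sets 60 were controls, which left 9275. Of these 6504 were annotated to 1 gene, 328 to several and 2443 to none. Of 5656 genes with a probe set of their own 315 had more than 1. Spearman correlations between arrays of the same group lay between 0.9676 and 0.9922, and the lowest between arrays of different groups was 0.9353. The highest share of identical values between 2 arrays was 0.343%.

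The 10th percentile of all signals, 16.9, was added to each signal before log2 was taken, and probe sets with a mean log2 signal at or under the 30th percentile were left out, which left 6492. Linear models were fitted with limma 3.58.1 (lmFit and eBayes with a trend) in R 4.3.3 with 1 mean per group and 10 residual degrees of freedom. The contrasts were H3del minus H3WT, H4del minus H4WT, the difference between these, and H3WT minus H4WT. P-values were adjusted by the Benjamini-Hochberg method over the tested probe sets, with a threshold of 0.05. Errors beside log2 fold changes are limma's standard errors. Gene lists were tested with camera of limma at a preset correlation of 0.01 and again with an estimated correlation, on the brightest probe set of each of 5121 genes. Of 39 lists 36 had at least 3 tested members. Tables were read and plotted with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

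The lists, thresholds, comparisons and the rule for naming genes were chosen before the data were examined. The rule names the 10 genes with the largest change each way past the threshold, without overlap between mutant and wild-type arrays, in each tail deletion. For the other contrasts it names 5 each way, for the difference without the overlap condition. It adds the histone, plasmid marker and silent mating-type genes, and the 4 members with the smallest adjusted p of each other list that passed camera or had at least 3 members past the threshold. For a gene with more than 1 probe set the brightest was used and the others are given beside it. Telomere-proximal genes are the 10 outermost open reading frames of each chromosome arm that have a probe set of their own, so some lie further in than the 10 outermost of all. Genes singled out beyond this rule, namely RPL27B, RPL7B, MFA1 and FDH1 in H4del, and the genes given for both deletions, were chosen after their values were seen.

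Arrays were hybridized on 5 days. Day 1 held H3del and H3WT replicates 1 and 2, day 2 held H4WT replicate 1 and H4del replicates 1 and 2, day 3 held H4WT replicate 2, day 4 held replicate 3 of all 4 groups, and day 5 held H3del and H3WT replicate 4. The day was fitted as a block (6 residual degrees of freedom) and within-day changes were computed where a day held both groups. H4WT replicate 2, alone on day 3, is wholly taken up by that block and does not enter the values fitted with it. To check whether replicate numbers pair the arrays, deviations from the group means were correlated between arrays. They lay between 0.263 and 0.638 for the 4 same-number pairs of the H3 strains, 0.278 and 0.520 for the 3 of the H4 strains and 0.268 and 0.501 for the 3 of the wild types, so the number was also fitted as a block (5 residual degrees of freedom). For 60 pairs of different days and groups they lay between -0.466 and 0.502. For all 13 pairs of the same day and different groups they lay between 0.263 and 0.638. The same-number pairs of the H3 strains are among these. Within day 1 H3del replicate 1 had 0.541 with H3WT replicate 2 and 0.356 with H3WT replicate 1. These values show that arrays of a day are alike, and do not show pairing by number beyond the day. The labels do not say whether arrays came from separate cultures, so p-values measure only the spread between these arrays.

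The fits were tested on simulated data in which 100 of 6492 probe sets changed 2-fold and 100 changed 4-fold. For H3del, H4del, the difference and the wild types 69%, 62%, 25% and 65% of the 2-fold and 96%, 95%, 82% and 99% of the 4-fold changes were recovered, with 12 false calls of 177, 8 of 165, 3 of 110 and 10 of 174. With the day as a block the recovery was 71%, 34%, 15% and 6% at 2-fold and 96%, 87%, 70% and 66% at 4-fold. Only the data simulated for that fit held an effect of the day. The recovery and false calls without a block are therefore not shown for arrays that differ by day. A simulated list of 20 raised genes was called by camera and 0 of 39 unchanged lists were. The simulated genes varied independently of each other, so this does not show how often lists of correlated genes are called falsely. In H3del the estimated correlation of the pheromone-induced list was 0.346. Alternatives tried were other pseudocounts (1 and 82.9), other filters, median centring, quantile normalization, no trend, stricter thresholds, the blocks, only the arrays compared, and leaving out each array. Leaving out the 4 arrays of day 4, using the day as a block in camera and counting the outermost genes among all annotated ones were chosen after seeing the data. The number of arrays limits the precision of all results. Probe sets below the filter were not tested except where the fit without it is named.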

Results

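The data are 14 expression arrays of budding yeast strains that lived on a single plasmid-borne copy of a core histone gene. In 4 arrays (H3del) histone H3 lacked residues 1 to 28 of its amino-terminal tail, and 4 arrays (H3WT) came from the matching strain with full-length H3. In 3 arrays (H4del) histone H4 lacked residues 2 to 26, and 3 arrays (H4WT) came from the matching strain with full-length H4. The histone tails are the flexible ends of the nucleosome's proteins and carry most of its acetylation and methylation sites. The H3 plasmid carried LEU2 and its strains grew without leucine and uracil, whereas the H4 plasmid carried TRP1 and its strains grew without tryptophan and uracil. Each array gave a signal for 9275 yeast probe sets, and 6492 of them were bright enough to be tested. The tested probe sets shared by the H3 genes HHT1 and HHT2 gave log2 fold changes of 0.15 ± 0.13 and -0.21 ± 0.25 (SE) in H3del. Another, too dim to be tested, gave 0.60 ± 0.30 in a fit of all probe sets. The probe set shared by the H4 genes HHF1 and HHF2 gave -0.88 ± 0.23 in H4del. Where the probes of these sets lie relative to the deleted residues is not given in the sources used here, so they do not check the labels. The number of arrays, 3 or 4 per group, limits the precision of every value below. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

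The comparison of H3del with H3WT asked which transcripts change when the H3 tail is removed. Among probe sets with a gene, the 3 largest decreases were in alpha-specific genes. MF(ALPHA)2, which encodes the alpha-factor pheromone, had a log2 fold change of -3.55 ± 0.21 (SE) and a signal of 292 ± 31.2 (SD, n = 4) against 3707 ± 1148 (SD, n = 4). SAG1, the alpha-agglutinin, had -2.47 ± 0.17 and STE3, the receptor for a-factor, had -2.40 ± 0.18. At the other end FDH1, a formate dehydrogenase, rose with a log2 fold change of 3.46 ± 0.17, YNR064C rose 10.6-fold, the sporulation gene SPO75 8.78-fold and FRM2, a nitroreductase, 8.30-fold. SNZ1 and SNO1, neighbouring genes of vitamin B6 synthesis, rose 6.36-fold and 6.07-fold. DAK2, a dihydroxyacetone kinase, rose 6.03-fold, and YAR068W, SPS2 and CPP3 rose between 5.09-fold and 5.74-fold. The adjusted p of these 13 genes lay between 1.1e-08 and 0.000234 in limma. The FDH1 probe set is of a kind that can hybridize to related sequences, and the other probe sets of FDH1 gave log2 fold changes from -0.00 to 2.78.

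Among the other largest decreases HO, the endonuclease of mating-type switching, had -2.22 ± 0.38 and FAR1, needed for arrest by pheromone, -2.03 ± 0.36. AGA1, the anchor subunit of a-agglutinin, had -1.91 ± 0.24 and SST2, which dampens pheromone signalling, -1.53 ± 0.34. ICS2, KTR2 and YDR222W had between -2.02 and -1.52. Of the 4 alpha-specific genes 3 fell and none rose, over all probe sets and adjusted over the list alone, with a mean log2 fold change of -2.16 (camera adjusted p = 3.51e-09, and 0.0105 with an estimated correlation). The remaining member was MF(ALPHA)1, the main alpha-factor gene, at -0.24 ± 0.13 (adjusted p = 0.347). Of 11 haploid-specific genes 2 fell, and 6 when adjusted over the list alone, with a mean of -0.80 (camera adjusted p = 3.56e-05, but adjusted p = 0.0792 with an estimated correlation). Of 12 pheromone-induced genes 5 fell, 6 when adjusted over the list alone, among them AGA1, SST2, PRM4 (-1.33 ± 0.19) and PRM1 (-1.27 ± 0.28). The mean of that list was -0.70 (camera adjusted p = 3.93e-05, and adjusted p = 0.166 with an estimated correlation). Of 4 a-specific genes 1, STE6 (0.66 ± 0.19), rose, and 3 when adjusted over the list alone, with a mean of 0.69 (camera adjusted p = 0.0147, and adjusted p = 0.0792 with an estimated correlation). HMRA1, the a1 gene at the silent locus HMR, lay below the brightness filter and had 0.48 ± 0.33 in the fit without the filter (adjusted p = 0.503), with a signal of 30.4 ± 11.3 against 17.2 ± 7.83. In limma the probe sets shared by the alpha1 genes of MAT and HML had -0.67 ± 0.22 and -0.46 ± 0.21 (adjusted p = 0.0757 and 0.239). Those shared by the alpha2 genes and HMRA2 had -0.42 ± 0.15 and -0.77 ± 0.27 (adjusted p = 0.111 and 0.104). With the day as a block the first alpha1 probe set (adjusted p = 0.00738) and both alpha2 ones (0.0350 and 0.0361) passed, and the second alpha1 one did not (0.0765).

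Of 16 seripauperin and DAN/TIR cell wall genes 12 rose, 13 when adjusted over the list alone, with a mean of 0.84 (camera adjusted p = 2.8e-10, and adjusted p = 0.0769 with an estimated correlation), for example TIR3 (1.55 ± 0.16) and TIR1 (1.03 ± 0.22). Of 14 glucose-repressed genes 8 rose, 9 when adjusted over the list alone, with a mean of 0.83 (camera adjusted p = 1.48e-08, and 0.0199 with an estimated correlation). They included MLS1, the malate synthase of the glyoxylate cycle (2.30 ± 0.23), ADH2, which oxidises ethanol (1.60 ± 0.18), CAT2 (1.59 ± 0.22) and FBP1 of gluconeogenesis (1.23 ± 0.20). Of 9 meiosis and sporulation genes 4 rose, 6 when adjusted over the list alone, with a mean of 0.80 (camera adjusted p = 0.000354, and 0.0417 with an estimated correlation), among them SPS2 (2.46 ± 0.26), SPS1 (1.71 ± 0.21) and RED1 (1.51 ± 0.40). Of 10 thiamine genes 3 rose, as also when adjusted over the list alone, with a mean of 0.55 (camera adjusted p = 0.000439, and adjusted p = 0.121 with an estimated correlation), led by THI4 at 1.29 ± 0.24. Of 10 DNA damage response genes 3 rose, as also when adjusted over the list alone: HUG1 (2.06 ± 0.19), RNR3 (1.26 ± 0.22) and RAD54 (0.76 ± 0.21), with a list mean of 0.47 (camera adjusted p = 0.00786, and adjusted p = 0.0655 with an estimated correlation). Of 29 heat shock genes 1 rose, as also when adjusted over the list alone, with a mean of -0.07, and the list did not pass camera (adjusted p = 0.563).

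Among the 253 tested open reading frames that were within the 10 outermost with a probe set of their own on a chromosome arm, 50 rose and 7 fell in H3del, or 56 and 12 when adjusted over the list alone. The mean of these telomere-proximal genes was 0.22 (camera adjusted p = 0.00056, and adjusted p = 0.153 with an estimated correlation). It was 0.33 over the 5 outermost, 0.15 over the 20 outermost, and 0.28 over the 158 tested when the 10 were counted among all annotated open reading frames (chosen after seeing the data), of which 38 rose and 6 fell. FDH1, HPF1 (2.00 ± 0.16), YNR071C (1.96 ± 0.19), POT1 (1.98 ± 0.22) and DAK2 were the members with the smallest adjusted p. Of 17 genes under nitrogen catabolite repression 3 rose, 4 when adjusted over the list alone: DAL1 (1.68 ± 0.19), DAL4 (1.24 ± 0.21) and DAL3 (1.16 ± 0.27) of allantoin use, with a list mean of 0.36 (camera adjusted p = 0.0201, and adjusted p = 0.464 with an estimated correlation). Of 7 hexose transporters HXT5 (1.86 ± 0.22) and HXT2 (1.05 ± 0.30) rose, over all probe sets and adjusted over the list alone (camera adjusted p = 0.0383, and adjusted p = 0.293 with an estimated correlation).

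Another 6 lists passed camera with a negative mean in H3del. Of 11 genes expressed at the M/G1 boundary 4 fell, 6 when adjusted over the list alone, with a mean of -0.56 (camera adjusted p = 2.97e-05, and 0.0417 with an estimated correlation). They were PCL9 (-1.08 ± 0.18), SCW11 (-1.07 ± 0.17), CTS1 (-0.82 ± 0.12) and DSE2 (-0.75 ± 0.16), of which SCW11, CTS1 and DSE2 act in cell separation. Of 8 phospholipid and inositol genes OPI3 fell (-0.50 ± 0.13), and 5 fell when adjusted over the list alone, with a mean of -0.41 (camera adjusted p = 0.00156, and 0.0417 with an estimated correlation). The sulfur and methionine list (mean -0.40, 1 of 21 fell, SUL2), the sterol list (-0.26, 2 of 21, ERG28 and ERG26), the zinc list (-0.43, 1 of 9, FET4) and the proteasome list (-0.16, 0 of 34) passed camera at adjusted p = 0.000723, 0.00609, 0.0147 and 0.0147. With an estimated correlation their adjusted p was 0.302, 0.249, 0.264 and 0.438. Adjusted over the list alone, 1, 2, 2 and 0 of their members fell, and of the proteasome genes 7 were lower at an unadjusted p under 0.05 in limma.

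Some of the lists whose own test did not pass held members that moved both ways. Of 10 phosphate genes 2 rose and 1 fell, 2 and 3 when adjusted over the list alone, PHO5, a secreted acid phosphatase, at 1.42 ± 0.20 and VTC4 at -0.69 ± 0.19 among them (camera adjusted p = 0.529). Of 17 iron genes 4 rose and 1 fell by both adjustments, among them FIT3 (1.39 ± 0.25), FIT1 (1.30 ± 0.18) and MRS4 (-0.93 ± 0.20) (camera adjusted p = 0.457). Of 6 NAD synthesis genes 3 rose and 1 fell by both adjustments, among them BNA4 (1.67 ± 0.18) and BNA1 (-0.65 ± 0.19) (camera adjusted p = 0.119). Of 5 COS family genes 2 rose, COS8 (1.08 ± 0.20) among them, and COS9 fell (-0.94 ± 0.21), likewise by both adjustments (camera adjusted p = 0.409). The probe sets of the histone genes gave no change past the threshold, including HTB1 (-0.19 ± 0.16), HTB2 (-0.30 ± 0.17) and HTZ1 (-0.41 ± 0.20). The plasmid marker LEU2 had 0.27 ± 0.34 and URA3 0.69 ± 0.19 (adjusted p = 0.0371).

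In all, 498 of 6492 probe sets passed an adjusted p of 0.05 in H3del against H3WT, 338 higher and 160 lower. Of these 471 had no overlap between the arrays of the groups, and 14.8% of all tested probe sets had none, against 2.86% by chance. With the hybridization day as a block 1338 passed, 732 higher and 606 lower, with all 498 among them. With the replicate number as a block 1047 passed, 619 higher and 428 lower, again with all 498. Without H3del replicate 1 the count was 330. Within day 1, day 4 and day 5 the alpha-specific mean was -2.38, -2.10 and -1.80, the haploid-specific mean -0.88, -0.49 and -0.92 and the glucose-repressed mean 0.85, 0.81 and 0.81. On the same days the seripauperin and DAN/TIR mean was 1.03, 0.55 and 0.77, the M/G1 mean -0.57, -0.51 and -0.58, the meiosis mean 0.87, 0.77 and 0.71, the telomere-proximal mean 0.30, 0.08 and 0.22, and the thiamine mean 0.47, 0.60 and 0.67. The pheromone-induced mean was -0.94, -0.40 and -0.50, the a-specific mean 0.74, 0.77 and 0.51, the DNA damage mean 0.47, 0.59 and 0.37, the phospholipid mean -0.44, -0.30 and -0.47, the nitrogen mean 0.62, 0.12 and 0.09, the hexose transporter mean 0.51, 0.31 and 0.71, the sterol mean -0.22, -0.40 and -0.21, the zinc mean -0.24, -0.75 and -0.50 and the proteasome mean -0.20, -0.15 and -0.10. The sulfur mean changed sign between days, at -0.49, -0.84 and 0.23. The zinc call was lost without the arrays of day 4 (mean -0.33, adjusted p = 0.0662). All 18 lists that passed camera also passed with the day as a block, which leaves these means as they are because both groups were on each of these days in equal number. With a block and an estimated correlation, where camera has 6 (day) or 5 (replicate) degrees of freedom in place of 10, no list passed. The 5 lists that had passed with an estimated correlation alone (alpha-specific, glucose-repressed, meiosis, phospholipid and M/G1) then had an adjusted p of 0.116 with the day block and between 0.0837 and 0.184 with the replicate block. The actin 3 prime over 5 prime ratio, a sign of RNA quality, was 2.89, 2.61, 1.54 and 2.74 on H3del replicates 1 to 4 against 1.95, 2.15, 1.56 and 1.94 in H3WT, and the TBP ratio was higher in H3del in replicates 2 to 4 (3.94, 3.84 and 4.94 against 2.47, 1.30 and 3.21) and lower in replicate 1.

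The comparison of H4del with H4WT asked the same of the H4 tail. The 2 largest decreases were in transcripts of the mitochondrial genome. OLI1, a subunit of the ATP synthase, had a mean signal of 2.33 (1.1 to 4, n = 3) in H4del against 5775 ± 4317 (SD, n = 3) in H4WT, a log2 fold change of -7.78 ± 0.75. COX1, a subunit of cytochrome c oxidase, had 4.50 ± 0.36 (SD) against 2454 ± 1628, a log2 fold change of -6.65 ± 0.48. Because the offset added before taking logarithms is larger than the H4del signals, these log2 values understate the ratio. Whether the H4del cultures held mitochondrial DNA is not known. Effects of the H4 tail on other genes can therefore not be told apart from effects of a loss of that DNA. FAR1 fell to a log2 fold change of -4.88 ± 0.42, RME1, a repressor of meiosis, to -4.67 ± 0.29, MF(ALPHA)2 to -4.24 ± 0.24 and MF(ALPHA)1 to -3.98 ± 0.15. FUS3, the pheromone-response kinase, had -3.98 ± 0.26 (its other probe sets -4.14 and -0.22), HO -3.76 ± 0.44 and STE18, a G protein subunit, -3.11 ± 0.22. YOR387C had -3.29 ± 0.93.

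All 11 haploid-specific genes fell in H4del, over all probe sets and adjusted over the list alone, with a mean log2 fold change of -2.93 (camera adjusted p = 1.96e-16, and 0.00601 with an estimated correlation). All 4 alpha-specific genes fell, likewise by both adjustments, with a mean of -3.43 (camera adjusted p = 1.4e-10, and 0.00597 with an estimated correlation), STE3 at -2.92 ± 0.21 and SAG1 at -2.57 ± 0.20 among them. HMRA1 had a signal of 758 ± 247 in H4del against 32.6 ± 24.0 in H4WT. It lay below the brightness filter over all arrays, and in the fit without the filter it rose by 4.06 ± 0.38 (adjusted p = 1.54e-05). The offset understates this value, because its H4WT signals of 6.1 to 52.8 were near the offset. Its other probe sets gave 1.13 to 1.96. The probe sets shared by the alpha1 genes of MAT and HML fell, at -1.35 ± 0.25 and -1.13 ± 0.25, and those shared by the alpha2 genes and HMRA2 did not pass (0.00 ± 0.17 and 0.08 ± 0.31). Of the 4 tested a-specific genes 1, MFA1, rose (1.25), and 1 rose and 1 fell when adjusted over the list alone, with a list mean of 0.15 (camera adjusted p = 0.245). Of 12 pheromone-induced genes 6 fell, and 6 fell and 1 rose when adjusted over the list alone, led by AGA1 (-2.15 ± 0.27), but the list did not pass camera (adjusted p = 0.177).

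The largest increases in H4del included non-coding RNA genes. RDN18-1, the 18S ribosomal RNA, had a log2 fold change of 3.29 ± 0.67, RDN5-3 2.22 ± 0.35 and the small nucleolar RNA genes SNR128 and SNR72 2.47 ± 0.31 and 2.14 ± 0.57. On the same arrays the 10 control probe sets for 18S and 25S ribosomal RNA averaged 2.20 ± 0.59 above H4WT, and in H3del 1.30 ± 0.51 above H3WT. The protein-coding genes were MPC3, a mitochondrial pyruvate carrier (2.59 ± 0.36), SPO75 (2.43 ± 0.21), SNO1 (2.43 ± 0.22), YPR078C (2.25 ± 0.22), SPO11, which makes meiotic DNA breaks (2.20 ± 0.21), and PUT1, the proline oxidase (2.14 ± 0.47). Of 9 meiosis and sporulation genes 2 rose, SPO11 and SPS4 (1.03 ± 0.29), as also when adjusted over the list alone, with a mean of 0.60 (camera adjusted p = 0.00104, and adjusted p = 0.0602 with an estimated correlation). Of 5 COS family genes, which lie near telomeres, 2 rose by both adjustments, COS8 (2.83-fold) and COS4 (0.65 ± 0.19), with a mean of 0.81 (camera adjusted p = 0.00392, and adjusted p = 0.0602 with an estimated correlation). The COS4 probe set is of a kind that can hybridize to related sequences, so it need not measure COS4 alone. The 253 telomere-proximal genes held 24 that rose and 35 that fell, or 28 and 37 when adjusted over the list alone, and did not pass camera (adjusted p = 0.193), whose direction was upward although the mean was -0.07 and the median -0.04. Counted among all annotated open reading frames 17 rose and 19 fell of 158, with a mean of -0.01, and camera passed upward before adjustment over the lists.

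Apart from the mating lists, 4 lists passed camera with a negative mean in H4del. Of 12 purine and one-carbon genes 8 fell, 11 when adjusted over the list alone, with a mean of -0.85 (camera adjusted p = 0.000478, and adjusted p = 0.518 with an estimated correlation), led by GCV1 of glycine cleavage at -1.49 ± 0.25 and ADE12 at -0.76 ± 0.14. Of 21 sulfur and methionine genes 8 fell, 10 when adjusted over the list alone, with a mean of -0.66 (camera adjusted p = 0.00222, and adjusted p = 0.549 with an estimated correlation), SUL1 (-1.32 ± 0.33) and MET3 (-1.27 ± 0.32) among them. Of 30 nuclear genes of the respiratory chain 8 fell, and 13 fell and 1 rose when adjusted over the list alone, with a mean of -0.47 (camera adjusted p = 0.00552, and adjusted p = 0.549 with an estimated correlation). The members with the smallest adjusted p were ATP16 (-1.30 ± 0.20), COX4 (-1.38 ± 0.23), ATP3 (-0.86 ± 0.18) and COX5A (-1.27 ± 0.27), on the same arrays on which COX1 and OLI1 were near 0. Of 9 zinc genes 4 fell, 6 when adjusted over the list alone, with a mean of -0.89 (camera adjusted p = 0.00392, and adjusted p = 0.377 with an estimated correlation). ZPS1 had -1.76 ± 0.49, and ADH4 had -1.47 ± 0.48 while its other probe set gave 1.46. Of 29 heat shock genes 8 fell, 9 when adjusted over the list alone, with a mean of -0.51, but the list did not pass camera (adjusted p = 0.102). Of 81 ribosomal protein genes 1 rose (RPL27B, 0.66 ± 0.19) and 2 fell (RPL7B, -0.93 ± 0.29, and RPL22B, -0.68 ± 0.20), none when adjusted over the list alone. The list's mean of 0.08 lay above the rest (camera adjusted p = 0.000971, and adjusted p = 0.609 with an estimated correlation) and turned to -0.03 under quantile normalization. The shared probe set of the H4 genes HHF1 and HHF2 was lower in H4del (-0.88 ± 0.23, adjusted p = 0.0187), and HHO1, the linker histone, fell (-0.87 ± 0.23).

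In all, 1134 probe sets passed in H4del against H4WT, 506 higher and 628 lower. This balance depended on the settings: without the filter 823 were higher and 624 lower, and without H4WT replicate 1 344 were higher and 321 lower. With only the arrays compared 315 were higher and 295 lower, among changes of at least 2-fold 275 and 206, and at an adjusted p of 0.01 195 and 189. Of the 1134 probe sets 1092 had no overlap between arrays, and 33.3% of all tested probe sets had none, against 10% by chance. With the day as a block 1933 passed, 809 higher and 1124 lower, with 1096 of the 1134 among them in the same direction. That fit rests on the other H4WT arrays, because H4WT replicate 2 was alone on day 3. With the replicate number as a block 2130 passed, 908 higher and 1222 lower, with all 1134. Within day 2 and day 4 the haploid-specific mean was -3.11 and -2.49, the alpha-specific mean -3.47 and -3.30, the purine mean -0.77 and -0.72, the sulfur mean -0.65 and -0.70 and the nuclear respiratory mean -0.44 and -0.46. The meiosis mean was 0.44 and 0.81, the COS family mean 0.93 and 0.76, the zinc mean -0.42 and -1.57 and the ribosomal protein mean 0.22 and -0.01. With the day as a block these 9 means were -2.84, -3.40, -0.75, -0.67, -0.45, 0.60, 0.85, -0.92 and 0.12, and all 9 lists passed at the preset correlation. With the day block and an estimated correlation none passed: the haploid-specific adjusted p was 0.125 and the alpha-specific 0.129, and 0.181 for both with the replicate block. Without the arrays of day 4 the zinc call was lost (mean -0.55, adjusted p = 0.153). COX1 had -6.98 and OLI1 -8.66 with the day as a block, again understated. The TBP 3 prime over 5 prime ratio was 3.21, 3.76 and 4.68 on H4del replicates 1 to 3 against 2.68, 3.20 and 3.15 in H4WT, and the actin ratio 1.99, 1.71 and 1.54 against 1.64, 1.82 and 1.48. The count depended on single arrays: it was 580 without H4WT replicate 2, 665 without H4WT replicate 1, 669 without H4del replicate 1 and 654 without H4del replicate 2. Without the 4 arrays of day 4, left out after seeing the data, it was 1751.

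**Figure D1:**
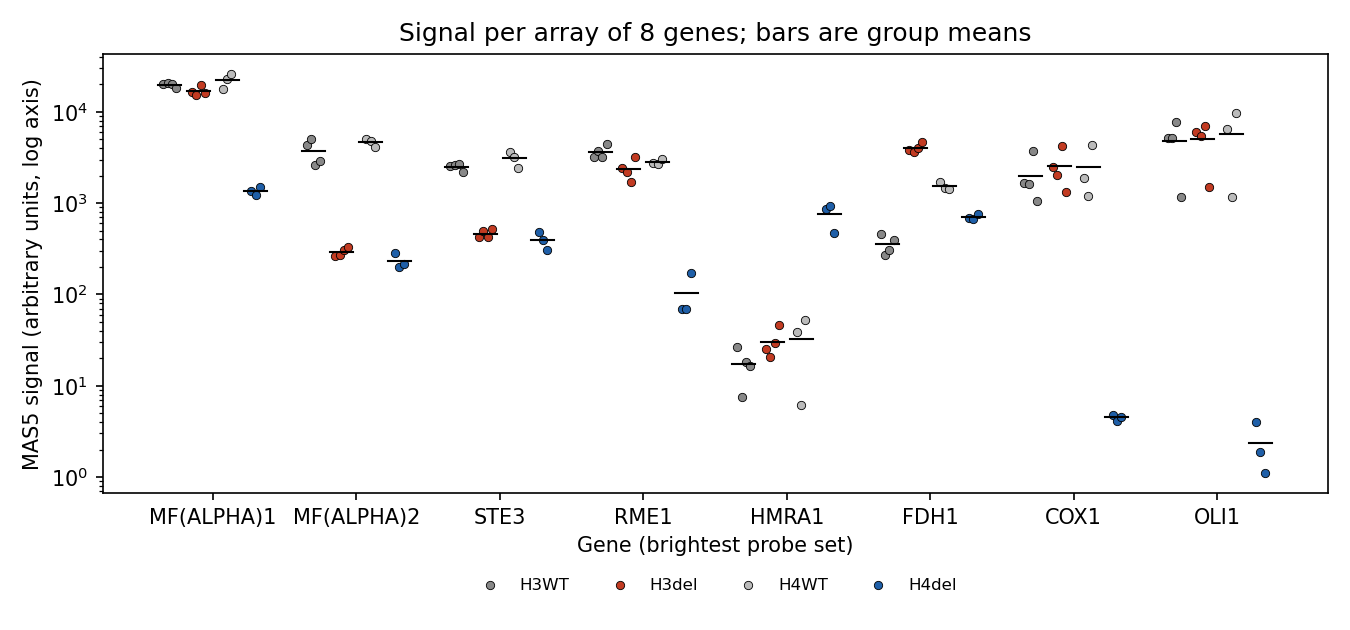
Signal of 8 genes on each of the 14 arrays (vertical axis, MAS5 signal in arbitrary units, log axis), with points for arrays, bars for group means, and colours for H3WT, H3del, H4WT and H4del. MF(ALPHA)2 and STE3 were lower in both tail deletions, MF(ALPHA)1 and RME1 had their lowest signals in H4del, HMRA1 averaged 758 in H4del, and COX1 and OLI1 averaged 4.50 and 2.33 there.

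Both deletions changed some of the same probe sets. Of the 498 and 1134, 163 moved the same way: 111 were higher in both, against 26.3 for independent lists (498 and 1134 probe sets split by direction), and 52 were lower in both, against 15.5. With the 50th percentile filter 36 were higher in both and 38 lower in both. Another 14 moved in opposite directions, against 45.2, and 11 of them were higher in H3del and lower in H4del. The contrasts share no control arrays. Genes lower in both included MF(ALPHA)2, SAG1, STE3, HO, FAR1, AGA1 and SST2, and genes higher in both included SPO75 (3.13 in H3del and 2.43 in H4del), SNO1 (2.60 and 2.43), FRM2 (3.05 and 1.76), YNR064C (3.40 and 1.61), CPP3 (2.35 and 1.38) and HUG1 (2.06 and 1.28). MPC3 (2.35 in H3del and 2.59 in H4del) and RDN18-1 (2.04 and 3.29) were also higher in both. Across the 6492 probe sets, which are not independent replicates, the log2 fold changes had Pearson's r = 0.371 and Spearman's rho = 0.322. With quantile normalization 98 probe sets were higher in both and 58 lower in both. The first quartile of all signals was 77 to 88.85 on H3del arrays against 63.9 to 68.05 in H3WT. It was 102.9 to 108.6 in H4del against 67.75 to 87.75 in H4WT. Whether a rise of dim probe sets common to both deletions gave part of the overlap or of the correlation was not tested. In all 418 probe sets moved the same way with the day as a block, 212 higher in both (91.2 for independent lists) and 206 lower in both (105). With the replicate number as a block 385 did, 220 higher (86.6) and 165 lower (80.6).

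The difference between the deletions was tested directly, as the H3del change minus the H4del change. A loss of mitochondrial DNA in the H4del cultures would enter these differences as well. Differences between the wild types enter them too, since each change is taken against its own wild type. SPO11, FDH1, MLS1, DAN1 and the seripauperin and DAN/TIR list differed between the wild types (below). The sign of a difference therefore need not be that of H3del against H4del themselves. OLI1 (7.90), COX1 (7.01), FDH1 (4.57 ± 0.27), RME1 (4.04 ± 0.38) and MF(ALPHA)1 (3.74 ± 0.20) had the largest positive differences. The fitted values of OLI1 and COX1 are understated, because their H4del signals lay under the offset. FDH1 rose in H3del and fell in H4del (-1.11), and the other 4 fell in H4del. The most negative were SPO11 (-2.30 ± 0.28), SNR73 (-2.14 ± 0.51), MRPL31 of the mitochondrial ribosome (-2.14 ± 0.30), NCA3 (-2.01 ± 0.43) and YGL204C (-1.97 ± 0.31). HMRA1, in the fit without the filter and near the offset in the other 3 groups, had -3.58 (adjusted p = 0.00151). The probe set of HHF1 and HHF2 had 1.35 ± 0.31 (adjusted p = 0.0249). Those shared by the alpha1 genes of MAT and HML had 0.67 ± 0.33 and 0.67 ± 0.32 and did not pass (adjusted p = 0.269 and 0.266 in limma).

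By list, 8 of 11 haploid-specific genes had a positive difference, 10 when adjusted over the list alone, with a mean of 2.14 (camera adjusted p = 1.11e-11, and 0.0419 with an estimated correlation, but adjusted p = 0.209 with that and the day block and 0.381 with that and the replicate block), NEJ1 (2.81 ± 0.37), FUS3 (3.26 ± 0.34) and STE18 (2.77 ± 0.29) among them. The alpha-specific mean was 1.26, with 1 of 4 genes past the threshold by both adjustments (camera adjusted p = 0.0137, and adjusted p = 0.249 with an estimated correlation), and this call was lost with the day as a block (adjusted p = 0.0765) and with the replicate block (adjusted p = 0.0697). Of 14 glucose-repressed genes 3 had a positive difference, 6 when adjusted over the list alone, among them MLS1 (3.29 ± 0.35) and ADH2 (1.94 ± 0.28), with a mean of 0.76 (camera adjusted p = 0.013, and adjusted p = 0.275 with an estimated correlation). The thiamine list had 3 of 10 and 7 of 10 by the same adjustments, with a mean of 0.90 (camera adjusted p = 0.000771). The seripauperin and DAN/TIR list had 2 of 16 and 5 of 16, with a mean of 0.88, and the purine list 1 of 12 and 8 of 12, with a mean of 0.86, both at the same camera adjusted p = 0.000771. With an estimated correlation the adjusted p of these 3 lists was 0.249, 0.487 and 0.487. Of 11 M/G1 genes 3 had a negative difference, 5 when adjusted over the list alone, PCL9 (-1.14 ± 0.27), SCW11 (-1.09 ± 0.26) and CTS1 (-0.90 ± 0.19), with a mean of -0.66 (camera adjusted p = 9.02e-06, and adjusted p = 0.0653 with an estimated correlation).

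In all, 239 probe sets differed between the deletions, 156 with a positive and 83 with a negative difference. The positive share was 65.3%, and it was 51.8% of 369 after quantile normalization and 55.0% of 278 after median centring. A total of 1078 passed with the day as a block (679 positive and 399 negative) and with the replicate number as a block 1056 (671 and 385), with all 239 in both. The count depended on single arrays: it was 137, 131 and 157 without H3del replicates 1, 2 and 4, 135, 131 and 466 without H4WT replicates 1, 2 and 3, and 125 and 117 without H4del replicates 1 and 2. It was 744 without the arrays of day 4. Day 4 alone held all 4 groups: there the haploid-specific mean was 2.00, the alpha-specific 1.20, the glucose-repressed 0.69, the thiamine 1.05, the seripauperin 0.53, the purine 0.71 and the M/G1 -0.56. With the day as a block these means were 2.04, 1.23, 0.78, 0.95, 0.87, 0.76 and -0.61, and the COS family (-0.61, adjusted p = 0.0201) and the ribosomal protein genes (-0.04, adjusted p = 0.0355) also passed, but not with the block and an estimated correlation (adjusted p = 0.342 and 0.733). With the replicate block the COS family passed too, at a mean of -0.57 (adjusted p = 0.0322, but adjusted p = 0.389 with an estimated correlation). Without the arrays of day 4 the glucose-repressed call was lost (mean 0.79, adjusted p = 0.0863).

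**Figure D2:**
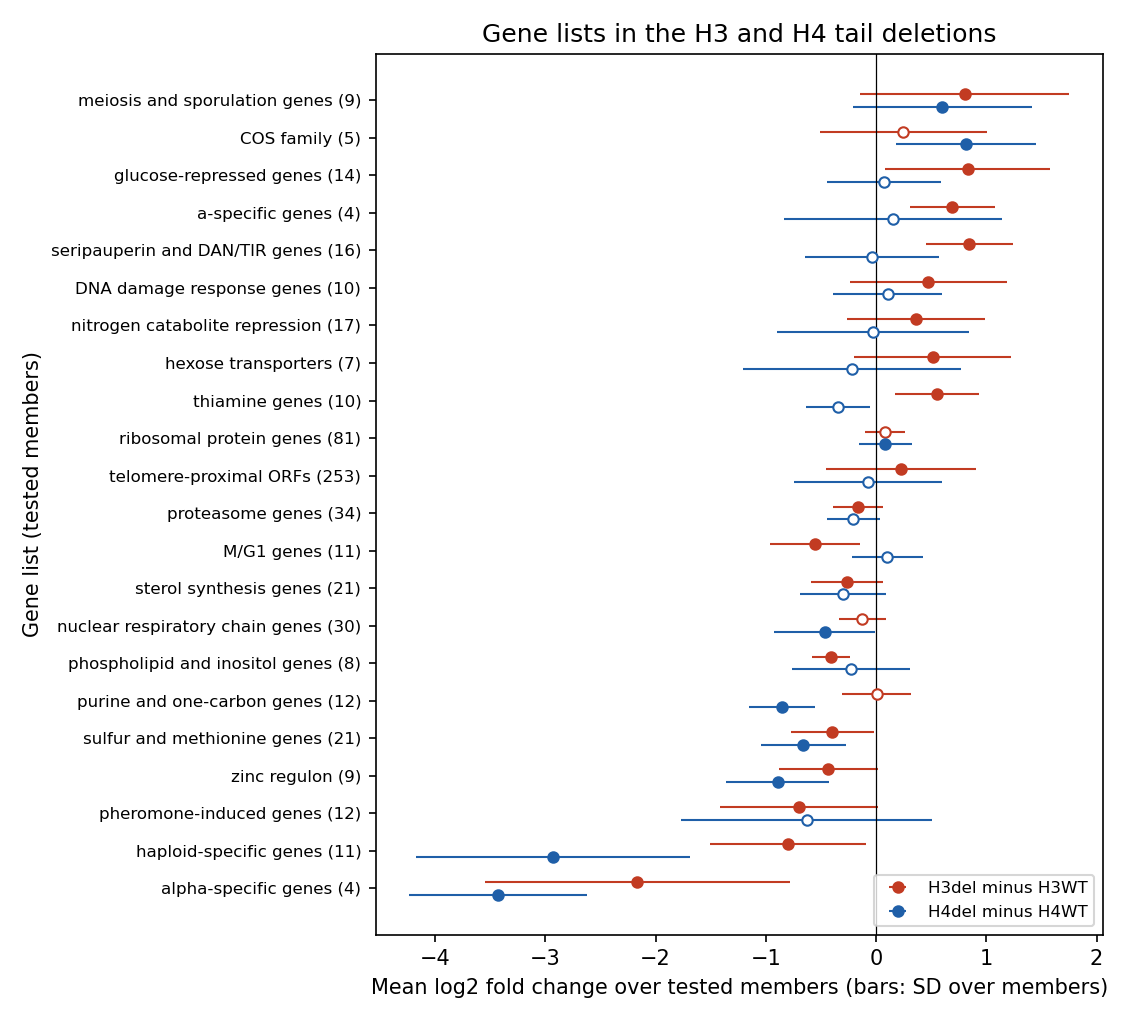
Mean log2 fold change (horizontal axis) of the 22 gene lists that passed camera in at least 1 tail deletion, with the number of tested members in brackets and bars for the SD over members. Filled circles passed at an adjusted p of 0.05 and open circles did not. The haploid-specific mean was -0.80 in H3del and -2.93 in H4del, and the seripauperin and DAN/TIR mean 0.84 and -0.04. The ribosomal protein mean in H4del, 0.08, turned negative under quantile normalization.

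The wild types, H3WT minus H4WT, differ in the histone gene on the plasmid, in the plasmid marker and in the amino acid left out of the medium. These cannot be told apart, and most of the arrays were also hybridized on different days. The markers followed the plasmids: LEU2 was higher in H3WT (2.33 ± 0.36, and 3.40 to 3.66 by its other probe sets) and TRP1 lower (-2.73 ± 0.26). SPO11 (1.95 ± 0.20), ICS2 (1.76 ± 0.30), ROQ1 (1.70 ± 0.45) and CUR1 (1.38 ± 0.21) were also higher in H3WT. DAN1 (-2.86 ± 0.50), SPG4 (-2.45 ± 0.32), PDC6 (-2.33 ± 0.23) and ANS1 (-2.11 ± 0.26) were lower. ROQ1 and ICS2 no longer passed with the day as a block (0.20, adjusted p = 0.699, and 1.05, adjusted p = 0.137).

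This contrast shares the 4 H3WT arrays with H3del minus H3WT, with opposite signs, and the 3 H4WT arrays with H4del minus H4WT, with the same sign. A value particular to 1 wild type enters both contrasts that use it, so their changes are not compared here. Such a value enters the difference between the deletions as well. For example, FDH1 signals were 271.8 to 456.8 in H3WT, 1438.7 to 1693.8 in H4WT and 3602.5 to 4649.5 in H3del. SPO11, higher in H4del than in H4WT, was also higher in H3WT than in H4WT. Of 16 seripauperin and DAN/TIR genes 14 were lower in H3WT, 15 when adjusted over the list alone, with a mean of -1.38 (camera adjusted p = 8.47e-27, and 0.028 with an estimated correlation). Of 14 glucose-repressed genes 4 were lower, as also when adjusted over the list alone, with a mean of -0.55 (camera adjusted p = 1.12e-06, and 0.0333 with an estimated correlation). FDH1 (-2.08 ± 0.19), MLS1 (-1.90 ± 0.25), HUG1 (-1.88 ± 0.21), SNZ1 (-1.85 ± 0.19) and THI4 (-1.73 ± 0.26) were lower in H3WT. Of 7 plasmid and strain markers 1 was higher and 2 lower, 1 and 6 when adjusted over the list alone (mean -0.44, camera adjusted p = 0.000473, and 0.0333 with an estimated correlation). Of 44 Gcn4 targets of amino acid synthesis 4 were lower, 7 when adjusted over the list alone, with a mean of -0.34 (camera adjusted p = 7.08e-08, and adjusted p = 0.192 with an estimated correlation), ARG1 (-0.89 ± 0.17) and ARG3 (-1.24 ± 0.25) among them. Of 10 thiamine genes 2 were lower, 3 when adjusted over the list alone (mean -0.46, camera adjusted p = 0.000446, and adjusted p = 0.192 with an estimated correlation). Of 34 proteasome genes 2 were higher, 3 when adjusted over the list alone (mean 0.29, camera adjusted p = 0.000465, and adjusted p = 0.311 with an estimated correlation), PRE4 (0.71 ± 0.16) and RPN14 (0.79 ± 0.19).

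Of 30 nuclear respiratory genes 3 were higher in H3WT, QCR10 (1.22 ± 0.21), SDH2 (0.96 ± 0.20) and SDH4 (0.79 ± 0.17), and 7 when adjusted over the list alone (mean 0.37, camera adjusted p = 6.67e-05, and adjusted p = 0.299 with an estimated correlation). That call was lost with the day as a block (mean 0.16, adjusted p = 0.169). So were those of the ribosome biogenesis genes, whose mean of -0.20 turned to 0.18 (camera adjusted p = 6.67e-05 without and 0.0939 with the block), and of the sulfur genes (-0.29 to -0.04, adjusted p = 0.00241 and 0.616). With an estimated correlation the adjusted p of these last lists was 0.42 and 0.356. Of the 56 ribosome biogenesis genes 0 passed in limma by either adjustment, and 1 was higher and 3 lower at an unadjusted p under 0.05.

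A further 7 lists passed camera between the wild types. Of 81 ribosomal protein genes 1 was lower in H3WT, and none when adjusted over the list alone, with a mean of -0.18 (-0.12 with the day as a block and -0.24 within day 4). Of 12 purine genes 0 passed in limma, 6 were lower at an unadjusted p under 0.05 and 5 when adjusted over the list alone, with a mean of -0.57 (-0.23 with the block, adjusted p = 0.0409, and -0.20 within day 4). Of 17 nitrogen genes 0 passed in limma by either adjustment and 4 were lower at an unadjusted p under 0.05, with a mean of -0.17 (-0.32 and -0.21). The telomere-proximal list had 4 of 253 higher and 28 lower, 12 and 36 when adjusted over the list alone, with a mean of -0.12 (-0.18 and -0.11). The meiosis list had 1 of 9 higher and 2 lower, 1 and 3 when adjusted over the list alone, with a mean of -0.40 (-0.56 and -0.44). Of 10 DNA damage genes 2 were lower by both adjustments, with a mean of -0.30 (-0.48 and -0.50), and of 11 M/G1 genes 1 was higher, 3 when adjusted over the list alone, with a mean of 0.40 (0.36 and 0.33). Their adjusted p with an estimated correlation lay between 0.192 and 0.447. The DNA damage genes no longer passed with the replicate block (adjusted p = 0.057). Without the arrays of day 4 the calls of the DNA damage, nitrogen, telomere-proximal and meiosis lists were lost (adjusted p = 0.360, 0.111, 0.0886 and 0.0886).

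With the day as a block and an estimated correlation no list passed between the wild types. The seripauperin and DAN/TIR and the glucose-repressed list had an adjusted p of 0.0674 and the markers 0.126, and all 3 had 0.133 with the replicate block.

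In all, 221 probe sets differed between the wild types, 80 higher and 141 lower in H3WT. The share higher was 36.2%, and it was 24.5% of 233 after median centring. When the day was a block 247 passed, with 130 of the 221 among them, and with the replicate number as a block 511 passed, 247 higher and 264 lower, with all 221. The count was 137 without H4WT replicate 1, 138 without H4WT replicate 2 and 666 without the arrays of day 4. Only day 4 held both wild types: there the seripauperin and DAN/TIR mean was -1.47, the glucose-repressed mean -0.71, the Gcn4 target mean -0.38, the thiamine mean -0.71, the marker mean -0.61, the proteasome mean 0.34, the nuclear respiratory mean 0.08, the ribosome biogenesis mean 0.30 and the sulfur mean 0.17. Another 6 lists passed only with the day as a block, and the heat shock list, whose mean of 0.21 had the sign opposite to its block value of -0.51 (adjusted p = 9.16e-07, but 0.230 with the block and an estimated correlation), was among them. Its mean without the arrays of day 4 was 0.53 (adjusted p = 0.00791 at the preset correlation, and not tested there with an estimated one). The other 5 had an adjusted p between 0.126 and 0.427 with the block and an estimated correlation.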

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

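The tests of explanations, other than the counts over other splits of the arrays, and the tests of the ribosomal RNA controls were chosen only after the result was seen. The search for single arrays apart and the tests of the difference were planned.

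Of 456 groups of 4 arrays tested (210 named probe sets and 18 quality measures in H3del and in H3WT), 30 had an array far from the other 3, and chance does this in about 1 in 20 groups. By array these were 14 on H3del replicate 3, 6 on H3WT replicate 3, 4 on H3WT replicate 4, 3 on H3del replicate 4 and 1 each on H3del replicates 1 and 2 and H3WT replicate 2. The replicate 3 arrays were hybridized on day 4. Below, each signal stands before the range of the other 3 arrays, with the gap divided by the whole range in brackets. On H3del replicate 3 these were the SRB4 3 prime over 5 prime ratio 5.99 against 48.1 to 49.2 (0.974), COS8 5276 against 8810 to 9342 (0.897), COS7 3180 against 515 to 662 (0.864), BAR1 228 against 379 to 393 (0.931) and HXT4 8606 against 3570 to 3862 (0.911). On the same array there were also CHO1 6677 against 4247 to 4301 (0.972), PET18 1159 against 1578 to 1631 (0.903), STE4 2883 against 3529 to 3656 (0.851), PCK1 756 against 487 to 515 (0.875) and INO1 9987 against 7180 to 7330 (0.938). The others on it were MPC3 472 against 672 to 703 (0.887), RPL27B 16050 against 10372 to 10911 (0.884), GDH3 1359 against 2091 to 2266 (0.843) and DMC1 293 against 586 to 652 (0.865). On H3WT replicate 3 these were 25S control probe set d 436 against 71.8 to 106 (0.905), FRM2 376 against 526 to 531 (0.973), ADE2 4012 against 7567 to 8594 (0.833), YNR071C 74.3 against 94.2 to 97.5 (0.871) and DAN1 63.7 against 84.3 to 88.1 (0.861). It also stood apart in MRPL31 1004 against 1472 to 1584 (0.838). On H3WT replicate 4 these were the dap spike 880 against 2.1 to 4.1 (0.998), PAU13 1446 against 1858 to 1914 (0.896), ALD3 546 against 270 to 305 (0.831) and SNR73 114 against 179 to 190 (0.883). On H3del replicate 4 these were 25S control probe set a 1311 against 13057 to 15345 (0.837), the dap spike 794 against 2 to 5.2 (0.996) and STE18 466 against 524 to 534 (0.857). Single values were SPB4 1576 against 1774 to 1816 (0.836) on H3del replicate 1, UGA4 200 against 170 to 172 (0.928) on H3del replicate 2 and YAR068W 24.9 against 91.3 to 113 (0.839) on H3WT replicate 2.

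The change differed between the tail deletions, by the limma test of the difference, for 57 of 182 named genes and for 7 lists. Many of the named genes were picked from these data by their changes, some of them by this difference. The share among them is therefore raised by the choice. Over all tested probe sets 239 of 6492 differed. Each value is the H3del minus the H4del log2 change, with the adjusted p in brackets. Positive differences were FAR1 2.85 (0.0127), YAR068W 2.14 (0.0368), RNR3 1.84 (0.00642), BAR1 2.14 (0.0419), POT1 1.92 (0.00551), THI4 1.61 (0.0246), DAK2 2.04 (0.0192), FIT1 1.08 (0.0419) and SPS2 1.89 (0.0176). Further positive differences were FRM2 1.29 (0.0192), PHO3 1.03 (0.0255), FUS3 3.26 (7.57e-05), BNA4 1.40 (0.0119), MF(ALPHA)1 3.74 (3.32e-08), FDH1 4.57 (4.81e-08), STE4 1.43 (0.0127), HPF1 0.96 (0.0451) and YNR064C 1.80 (0.0299). Others were YNR071C 1.69 (0.00522), MLS1 3.29 (7.82e-05), ADH2 1.94 (0.00121), SNZ1 2.10 (0.000606), CAT2 1.79 (0.00874), DAN1 3.30 (0.0192), STE18 2.77 (7.82e-05), OLI1 7.90 (0.000424) and COX1 7.01 (2.06e-05). Positive too were IRC24 1.37 (0.0172), SER33 1.10 (0.0454), RME1 4.04 (2.53e-05), ATP16 1.15 (0.0242), VBA2 1.16 (0.0161), SUL1 1.88 (0.0263), HSP26 1.57 (0.0302), TIR4 1.96 (0.00314) and LYS9 1.47 (0.00608). The last positive ones were ADE12 0.74 (0.033), RRP5 1.07 (0.0255), NEJ1 2.81 (0.000632), GDH3 1.35 (0.0153), SSA3 3.05 (0.00222), THI22 1.17 (0.0202) and GRE1 1.39 (0.0323). Negative differences were CTS1 -0.90 (0.0185), BNA1 -1.52 (0.00979), TNA1 -1.04 (0.0454), SCW11 -1.09 (0.0267), PCL9 -1.14 (0.0269), HMRA1 -3.58 (0.00151), SNR128 -1.59 (0.0454), URA1 -0.67 (0.0269) and RDN5-3 -1.78 (0.0432). Also negative were SPO11 -2.30 (0.000373), MRPL31 -2.14 (0.00108), NCA3 -2.01 (0.0192), YGL204C -1.97 (0.00213) and SNR73 -2.14 (0.0283). Of the lists these were alpha-specific genes 1.26 (0.0137), haploid-specific genes 2.14 (1.11e-11), glucose-repressed genes 0.76 (0.013), purine and one-carbon genes 0.86 (0.000771), thiamine genes 0.90 (0.000771), seripauperin and DAN/TIR genes 0.88 (0.000771) and M/G1 genes -0.66 (9.02e-06), tested with camera. With an estimated correlation only the haploid-specific list passed (adjusted p = 0.0419), a call lost when the day (adjusted p = 0.209) or the replicate number (adjusted p = 0.381) was a block as well, and the others had an adjusted p between 0.0653 and 0.487. The alpha-specific call was also lost with the day as a block (adjusted p = 0.0765) and with the replicate block (adjusted p = 0.0697). HMRA1 was tested in the fit without the filter, and its value, like those of OLI1 and COX1, depends on the offset.

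The control probe sets for ribosomal RNA, outside the comparisons of the genes, were higher in H4del than in H4WT: the 5 for 18S by a mean log2 change of 2.42 ± 0.56 (SE) and the 5 for 25S by 1.97 ± 0.63. The exact permutation p was 0.1 for each, the smallest that 3 against 3 arrays can give. In H3del the values were 1.34 ± 0.48 and 1.27 ± 0.55 (exact permutation p = 0.0571 for each, where the smallest possible is 0.0286). That p leaves the pairing of the arrays aside. All 4 pairs of the same number were higher in H3del, for which the exact paired permutation p is 0.125, the smallest possible, and with the day as a block the values were 1.34 ± 0.30 and 1.27 ± 0.20. In H4del all 3 pairs were higher (exact paired permutation p = 0.25, the smallest possible), and the values with the block were 2.01 ± 0.39 and 1.43 ± 0.26.

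The counts were set against other splits of the same arrays. For H3del against H3WT 1 of 35 splits, the real one, gave as many as 498 probe sets and the highest other gave 0. That excludes chance only if the arrays are taken as unpaired. Among the 8 splits that part as many pairs, too few for a share under 0.05, the highest other also gave 0. For the wild types 1 of 35 gave as many as 221, and the highest other gave 25. The same limit holds, as the real split is 1 of 8 that part as many pairs, of which the highest other gave 0. For probe sets changed the same way by both deletions 1 of 100 drawn splits gave as many as 163, and the highest other gave 0. That count is fixed at 0 where a split calls none in 1 of the deletions, and 0 of the other splits called any in both, so it cannot tell chance from sharing. For H4del against H4WT 1 of 10 splits, the real one, gave 1134 and the highest other gave 0, and 10 splits are too few for a share under 0.05. For the difference between the deletions 6 of 100 drawn splits gave as many as 239, and the highest other gave 512, so chance is not excluded for that count. All 5 of those other splits keep the H4del arrays apart from the H4WT arrays, as 10 of the drawn ones do, and so hold the whole H4 change. Of these 5, 2 part the H3 strains by day 1 against the other days (455 and 346). The highest count among splits that mix the H4 groups was 30.

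The haploid-specific genes were lower in H4del beyond their change in H3del. The hybridization day is argued against: the mean difference was 2.04 ± 0.20 (SE between arrays) with the day as a block and 2.14 ± 0.26 without it, though the camera call with the block (adjusted p = 1.67e-08) was lost with an estimated correlation (adjusted p = 0.209), where camera has 6 degrees of freedom. Cells of the a mating type in the H4del cultures are argued against too, since they also express the haploid-specific genes, which fell by -2.93 ± 1.24 (SD over genes), and the 7 a-specific genes had a mean log2 fold change of 0.0743 ± 0.73, although MFA1 alone rose (1.25). Expression of HMRA1, whose product together with alpha2 represses haploid-specific genes, may account for it. Its signal was 476 to 935 in H4del against 6.1 to 52.8 in H4WT, a fitted rise of 4.06 ± 0.38 (SE) that the offset understates. In H3del it was 20.7 to 46.4 against 7.6 to 26.7 in H3WT, near the offset in both. Diploid cells in the H4del cultures cannot be told apart from expression of HMRA1, because the alpha1 probe sets fell by -1.24, which both would give.

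COX1 and OLI1 were near the floor on the H4del arrays. The hybridization day is argued against, since the smaller change within day 2 and day 4 was -7.41, understated by the offset, while the arrays of the other groups differed by -1.71 between days 3 and 5 and the rest. Loss of the mitochondrial DNA in the H4del cultures stays open: all 4 mitochondrial probe sets with a mean H4WT signal over 100 fell, the least by -2.21, but 3 are annotated to COX1 (2 of them also to the intron genes AI5_ALPHA or AI4) and 1 to OLI1, so they hardly test other genes. Of the 6 dimmer genes COX3 (-1.91), COX2 (-1.10) and COB (-1.51) also fell, which such a loss would give. The offset understates these values: mean signals were 4.87 in H4del against 68.1 in H4WT for COX3, 5.83 against 32.6 for COX2 and 4.63 against 48.7 for COB. ATP6 did not pass, at 3.03 against 40.1. VAR1 and ATP8 did not pass either, at 11.8 against 19.9 and 9.57 against 15.3, near the offset in both groups. Whether such a loss came with the tail deletion or from a clone without mitochondrial DNA cannot be told apart, as the highest H4del signal of 4.8 would follow from both and the labels do not say whether the cultures were separate.

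The rRNA control probe sets were brighter on the H4del arrays. Scaling is argued against, since the mean log2 change was 2.20 after quantile normalization (1.11 in H3del), and the day as well, since it was 1.72 ± 0.31 with the day as a block (1.30 in H3del). A higher background is argued against, as the median rise was 1439 in signal while the first quartile of all signals rose by 26.6. More rRNA in the labelled RNA of the mutants, at 2.20 ± 0.59 without a block, could be a cause, but cannot be told apart from a change in the cells, because RNA yield and rRNA share are not given in the sources used here.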

How the results depend on the processing

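The analyses without day 4, with the day as a block in camera and with the outermost genes counted among all annotated ones were chosen after seeing the data. Counts below are for H3del, H4del, the difference, the wild types and both deletions the same way, in that order (498, 1134, 239, 221 and 163). They stayed within 1.5 times with a pseudocount of 1 (498, 1126, 242, 230, 160) or 82.9 (501, 1152, 251, 216, 167), no filter (690, 1447, 273, 264, 231), median centring (503, 1111, 278, 233, 175) and no trend (507, 1110, 264, 241, 169). Where they moved further, the cause was not tested unless fewer arrays, fewer probe sets or a stricter threshold gives it. With the 50th percentile filter H3del had 250 (137 higher and 113 lower), the wild types 135 and both 74. With quantile normalization the difference had 369, and the correlation was 0.336 against 0.371. With only the arrays compared H4del had 610 and the wild types 108. The replicate block gave 1047, 2130, 1056, 511 and 385, and for single calls it changed none but those named in the report, 53 of 354 gene results that came to pass, and the heat shock list in H4del (adjusted p = 0.0417, at the preset correlation only). The day block gave 1338, 1933, 1078 and, for both, 418. Without the 4 arrays of day 4 H4del had 1751, the difference 744 and the wild types 666. At least 2-fold were 264, 481, 133 (wild types) and 76 (both). At an adjusted p of 0.01 there were 269, 384, 50, 105 and 67. More were lower than higher in H4del (628 and 506), and this turned without the filter (624 and 823), with only the arrays compared (295 and 315), without H4WT replicate 1 (321 and 344), at least 2-fold (206 and 275) and at an adjusted p of 0.01 (189 and 195). For both deletions more were higher (111 and 52), and this turned with the 50th percentile filter (36 and 38). The cause of these turns was not tested.

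Leaving out 1 array gave 330 (without H3del replicate 1) to 480, 580 (without H4WT replicate 2) to 1492 (without H4WT replicate 3), 117 (without H4del replicate 2) to 466 (without H4WT replicate 3), 137 (without H4WT replicate 1) to 304, and 109 to 191, and correlations of 0.328 to 0.403. H4del had 665 without H4WT replicate 1 and 669 and 654 without H4del replicates 1 and 2, and the wild types 138 without H4WT replicate 2. The difference had 137, 131 and 157 without H3del replicates 1, 2 and 4, 135 and 131 without H4WT replicates 1 and 2, and 125 without H4del replicate 1.

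The mean of the ribosomal protein genes in H4del turned to -0.0324 under quantile normalization, and the ribosome biogenesis genes between the wild types turned upward with the day as a block (adjusted p = 0.0939). The cause was not tested for either. For H3del, H4del, the difference and the wild types 18, 9, 7 and 16 lists passed at the preset correlation. Of these 5, 2, 1 and 3 also passed with an estimated one, so of 144 set tests 39 no longer passed. With the day as a block 3 no longer passed, 8 came to pass and 1 turned, and without day 4 7 no longer passed and 11 came to pass. Of 144 list means 9 no longer passed and 1 came to pass under quantile normalization. Of 354 gene results 17 no longer passed and 6 came to pass under median centring, 16 and 6 under quantile normalization. With 1 array left out 328 of 2931 gene results no longer passed and 44 came to pass, and of 1260 list means 24 and 45. The 5 outermost genes per arm gave a camera p of 0.0139 in H4del, and the 10 outermost among all annotated genes gave 0.0108. Signals near the offset of 16.9 limit small changes in dim probe sets.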

Other observations

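The groups of this part were chosen only after the result was seen.

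Small nucleolar and nuclear RNA genes, which guide RNA modification and splicing, were put together after SNR128 and SNR72 were seen among the largest increases, so no test of the group is given. Of 24 tested 18 rose in H4del, 6 did not pass and 0 fell in limma (0 were lower and 23 higher at an unadjusted p under 0.05), with a mean log2 fold change of 1.45. SNR128 had 2.47 ± 0.31 (SE), SNR72 2.14 ± 0.57, SNR73 2.03 ± 0.38, SNR5 1.87 ± 0.23, SNR71 1.74 ± 0.22 and SNR61 1.73 ± 0.29. In H3del 1, SNR9 (0.93), rose and the mean was 0.39. The difference between the deletions had a mean of -1.06, with 5 of 24 genes past the threshold: SNR128, SNR71, SNR4, SNR5 and SNR73. On the same H4del arrays the 10 ribosomal RNA control probe sets averaged 2.20 ± 0.59 above H4WT.

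Probe sets annotated to no gene also moved in H4del. Of 804 tested 200 were higher and 32 lower, with a median of 0.46 (0.36 with the day as a block), while of 5430 with 1 gene 266 were higher and 584 lower, with a median of -0.14. In H3del 61 were higher and 18 lower, with medians of 0.15 and -0.01. Brightness moved alongside: of 10 classes of mean signal, from dim to bright, class 2 had a median of 0.40 in H4del, where 61.4% had no gene, and class 8 had -0.23, where 5.39% had none. The relation was not monotone: class 1 had 0.19, where 64.0% had no gene, and class 10 had 0.08, where 13.3% had none. In H3del class 2 had a median of 0.17 and class 8 one of -0.04.

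Of 6 dimmer genes of the mitochondrial genome 3 were lower in H4del in the fit without the filter, COX3 at -1.91 ± 0.30, COX2 at -1.10 ± 0.21 and COB at -1.51 ± 0.45, while ATP6 (-1.26, adjusted p = 0.128), VAR1 (-0.41, adjusted p = 0.540) and ATP8 (-0.27, adjusted p = 0.472) did not pass. The offset, larger than their H4del signals, understates these changes. The SRB4 3 prime over 5 prime ratio was 5.99, 8.44, 8.35 and 5.76 on the H3del, H3WT, H4WT and H4del arrays of day 4, against 9.29 to 91.0 on the other 10. The TBP ratio was higher on all 3 H4del arrays (3.21 to 4.68) than on the H4WT arrays (2.68 to 3.20), and both the TBP and the actin ratio were higher in H3del in 3 of 4 pairs of the same number. The dap spike was 794 and 880 on the arrays of day 5.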
